A study of Xenopus laevis with 27 samples.

How the data were processed

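RNA was sequenced from 3 tissues of adult Xenopus laevis frogs, a limb blastema, the limb stump and the brain, in 3 treatment groups, with 3 libraries in each of the 9 groups and 27 libraries in all. Per the labels, total RNA was isolated with TRIzol, ribosomal RNA was depleted from 1 µg of it with a human, mouse and rat RiboZero Gold kit, libraries were made with a Kapa HyperPrep kit for RNA, using 10 amplification cycles, and 40 nt were read on a HiSeq2000. The submitters' processing notes name FastQC, Trimmomatic, STAR, RSEM and edgeR as tools of the authors, without versions. The genome build, the annotation and the strand setting are not given in the sources used here, and no coordinates are printed. X. laevis is allotetraploid, and the 2 homeologous copies of a gene carry the suffixes .L and .S in the gene names of the tables.

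The authors deposited 9 tables, one per pair of treatments within a tissue. Each table holds, per the file headers, a value for every library and the authors' own comparison. The unit of the library values is not stated. They are taken here as FPKM made by the authors with RSEM, because value times gene length sums to the same total in every library, which FPKM does and TPM does not. The FPKM values of a library are equal in all 9 tables. The deposited group means are a signal that the headers call average CPM, and their scaling, inferred from the values, was by the upper quartile. The deposited q-values and p-values come from the authors' test, whose kind is not stated, and the deposited log2 fold changes carry the sign of the authors' order of groups. The tables name 42903 genes, of which 12143 have no gene name, and 0 library columns were left unused.

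The tests fixed before the data were examined assumed read counts. The tables hold FPKM, so the test fixed for that case was used: limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with group means and no block, all samples of a tissue in one fit, genes with FPKM of at least 1 in at least 3 samples, trend and robust options off, and a Benjamini-Hochberg adjusted p under 0.05. Fold changes are therefore on the log2(FPKM + 1) scale, which can understate the change of low genes. It can also overstate their change where a shallow library lists a gene at 0. The comparison of blastema with stump without a device had been set to run on counts only and was not run. The difference between blastema and stump effects was tested in one fit of the limb samples. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The 32 lists hold 1241 symbols, of which 1029 (82.9%) were found, and lists with fewer than 5 tested members were not tested.

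Gene lengths and read numbers were estimated from the FPKM values and the deposited group means. On simulated tables the median error of the estimated reads was 0.0011%. Those tables held whole reads and unscaled group means, unlike the deposited ones, so this does not measure the error of the real estimates. The estimated depth ran from 178318 to 3464017 reads per library, and an FPKM of 0.289 to 5.61 was then worth 1 read in a gene of 1 kb. Of the low values, 52.2% to 60.1% lay within 0.1 of a whole read, so whole reads were not recovered and no edgeR or DESeq2 fit was run. The chi-square tests of library pairs and of the smad4.1.S shares treat the estimated reads as counts. Their counting error is therefore approximate. The estimated reads entered voom, the read filters and the test of library pairs. Voom took the total of the estimated reads as the size of a library, with no scaling factors. A shift of all genes between groups therefore enters its calls. An FPKM of 0 in a shallow library can stand for a gene with several FPKM, so genes listed at 0 in a whole group are described as listed at 0. Single gene copies with near-identical sequence share reads of 40 nt, and their values are uncertain.

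Libraries of a tissue were compared in pairs by a chi-square test of the estimated reads per gene, over genes with at least 20 reads in the pair, with a Benjamini-Hochberg adjusted p under 0.05. Simulated pairs with sampling noise alone had 0% of genes past this threshold, and a gene-wise spread of 20% gave 1.03% in blastema, 4.15% in stump and 4.96% in brain. Pairs with fewer than 1% of genes past it were called near-identical. The 1% limit was set after the pairs had been seen, and the fit of 9 separate libraries had been run before the merging was decided. Near-identical libraries of the same group were averaged and counted as 1 sample, so n is 2 for the blastema progesterone, stump no-device and brain no-device groups and 3 for the others. The library labelled brain silk 3, near-identical to 2 brain no-device libraries, was kept in its group and counted apart from them. The merging was kept although it took the counts of genes to 0 in most comparisons, and the counts with separate libraries are given beside them. The labels do not say whether libraries came from separate animals, and p-values measure the spread between these samples, which may be technical.

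Genes were named by a rule set before the data were examined: the largest changes among passing genes, passing members of lists that passed, and copies of pgr, fkbp5, klf9, tsc22d3 and zbtb16 in any case. Where fewer than 5 genes passed, the 5 named genes with the smallest p are given as not passing. Members of lists that did not pass on their own, with the smallest p of their list, were chosen after their values were seen. The genes printed are a part of those the rule names, picked when their values and the alternatives had been seen.

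The power of the limma test was checked on simulated data with 40 changed genes at each fold size. In blastema, 52.5% of genes changed by log2 5 and 7.5% of those changed by log2 3 were recovered among 37273 genes, against 92.5% and 57.5% among the 8546 genes with a mean of at least 10 estimated reads. In stump, 67.5% and 17.5% were recovered among 29972 genes, against 80.0% and 50.0% among 12855 genes. In brain, 90.0% and 82.5% were recovered among 27157 genes. Of the fixed lists, 0 passed in data simulated without change. The simulated genes varied independently of each other, so this does not check the preset correlation used for the real lists. A change of log2 2 was recovered in 0% of genes in both limb tissues among all genes tested, so absent calls in the limb are weak evidence.

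The alternatives listed before the data were examined and run were no filter, a stricter filter, limma-voom on estimated reads, only the samples of the compared groups, summed homeologs, a fold threshold of 1.5, a pseudocount of 0.1 in place of 1, trend and robust options, and each library left out. The replicate block was listed too, but was run only with separate libraries, since a merged sample has 2 replicate numbers. Added after seeing the data were separate near-identical libraries, the block with these, a mean of at least 10 estimated reads, median-of-ratios and upper-quartile scaling, a pseudocount of 5, voom with at least 5 or 10 reads, and leaving out a merged sample. For shared controls, 100 simulations of unchanged groups were run. Tables were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.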

Results

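The series measured gene expression after amputation of the hindlimb in adult Xenopus laevis, a frog that regrows little of its limb as an adult. Its title concerns a wearable bioreactor, a device that applies progesterone locally for a short time, and the long-term regenerative response. The 3 treatment groups are progesterone in the device, the silk device without the hormone as a sham, and no device. Each group was sampled in blastema (the tissue that forms on the amputation surface), stump and brain, with 3 libraries per tissue and treatment. The labels give no time of sampling and do not say which frogs gave which tissues.

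Estimated depth differed between groups. Blastema libraries held 220007 to 295138 reads with silk, 178318 to 952455 with progesterone and 405475 to 672294 without a device. In stump the ranges were 305007 to 678382 with silk, 493932 to 1699882 with progesterone and 2025454 to 3464017 without a device. In brain they were 646117 to 1846845, 1628131 to 2078940 and 1389911 to 1883549 in the same order. One gene model, smad4.1.S (named for a signal transducer of the TGF-beta family), took 22.1%, 38.5% and 39.3% of the estimated reads of the blastema silk libraries and 25.7% in blastema progesterone 2. Its share was 20.7% and 31.1% in stump silk 1 and 2, 16.0% in stump progesterone 1, and 11.5% and 10.2% in brain silk 1 and 2. Other device libraries had lower shares: 2.014% and 4.01% in blastema progesterone 1 and 3, 0.713% in stump silk 3, 0.961% and 2.027% in stump progesterone 2 and 3, 0.755% in brain silk 3 and 0.558% to 0.619% in brain progesterone libraries. Without a device the share was 0.520% to 1.099% in blastema and 0.0517% to 0.128% in stump and brain. The ranges overlap only across tissues: within each tissue every device library had a larger share than every library without a device.

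**Figure D1:**
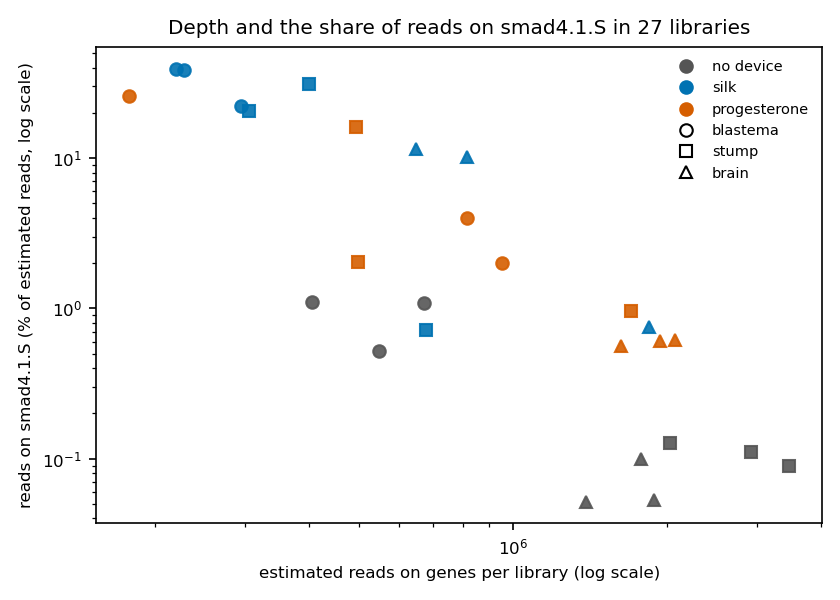
Each point is 1 of the 27 libraries, with its estimated number of reads on the x axis and the percent of these reads assigned to smad4.1.S on the y axis, both on log scales, and colour and shape giving treatment and tissue. Libraries with over 10% of reads on this gene model lie between 178318 and 812205 reads.

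Some libraries were nearly alike. Blastema progesterone 1 and 3 differed at 0.611% of 12444 genes, stump no-device 1 and 3 at 0.41% of 14160 genes, and brain no-device 1 and 3 at 0.317% of 18944 genes. Other pairs within a group differed at 6.69% to 23.7% of genes in blastema, 9.12% to 31.6% in stump and 1.56% to 10.7% in brain. The library labelled brain silk 3 differed from brain no-device 1 at 0.297% and from brain no-device 3 at 0.352% of genes. The near-identical pairs within a group lay between simulated noise and a 20% spread, in blastema nearer the spread. Each was counted as 1 sample. The library labelled brain silk 3 was kept in its labelled group.

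**Figure D2:**
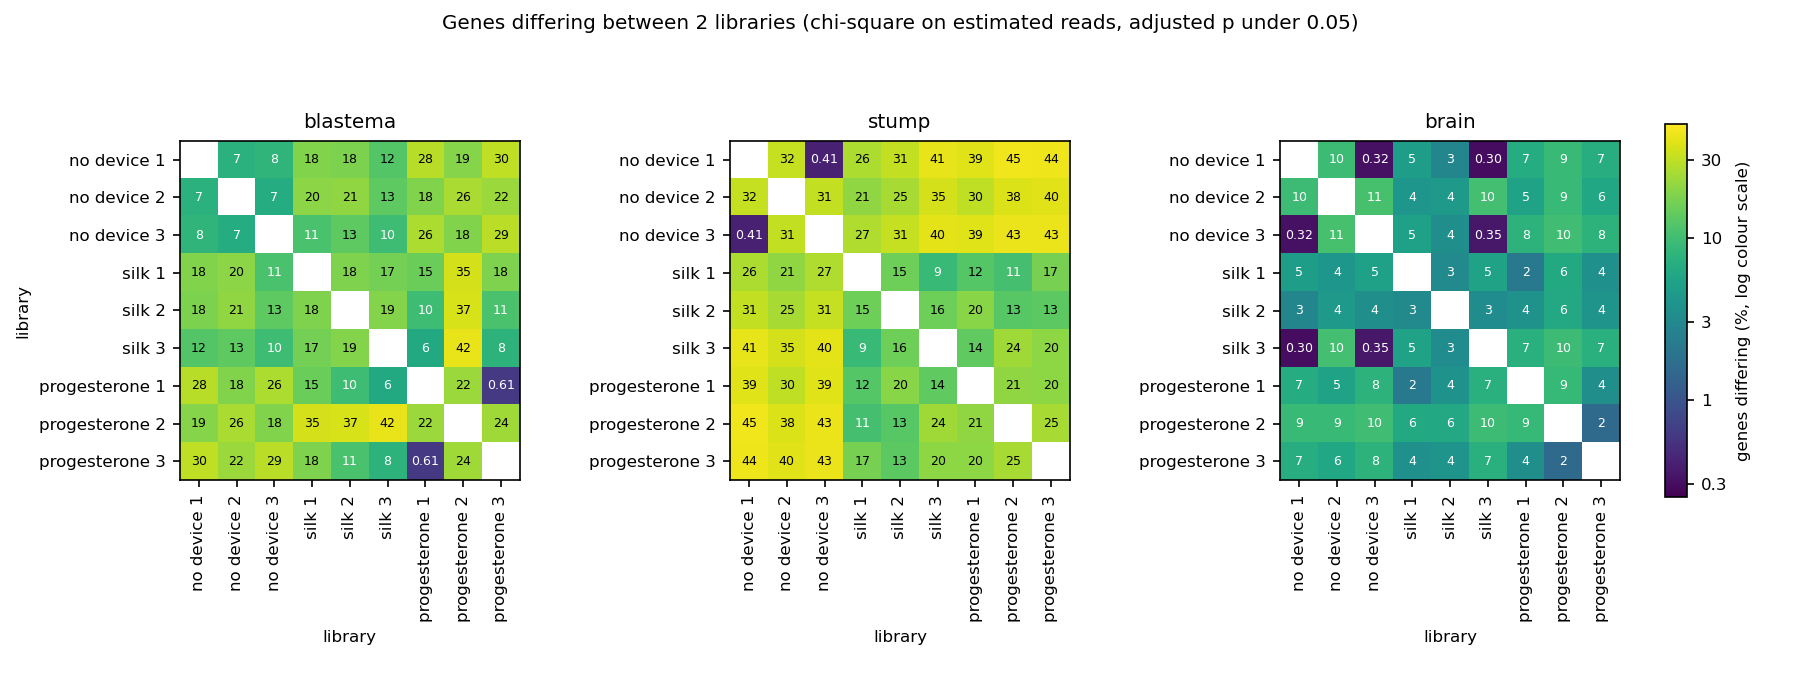
Each square gives the percent of genes that differ between a pair of libraries of a tissue by a chi-square test of estimated reads, on a log colour scale, with the libraries of the tissue on both axes. The 5 pairs that differ least, 1 in blastema, 1 in stump and 3 in brain, lie between 0.297% and 0.611%.

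Differences below are log2(FPKM + 1) values with standard errors, levels are mean FPKM ± SD over samples or ranges over samples, and medians of gene lists are relative to the median of all tested genes. That reference is needed because scaling moved the median of all genes. For silk minus no device it was −0.36 in blastema, 0.52 in stump and −0.14 in brain, and −0.14, 0.06 and −0.03 after median-of-ratios scaling. For progesterone minus no device in stump it was 0.57 and then 0.08, for progesterone minus silk in blastema 0.33 and then 0.17, and for the difference of the silk effects between blastema and stump −0.85 and then −0.24. Where leaving out 1 sample moved a list median or a printed difference by over 1.5 times, its range over these fits is given. Counts of positive or negative list members use differences not set relative to all genes, so a shift of all genes moves these counts too. In stump against no device the median of all genes was positive, so most tested genes were positive there. List tests are camera with a preset correlation, and no list passed with an estimated correlation in any comparison.

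The effect of the silk device on the blastema was examined by comparing silk with no device (n = 3 and n = 3). Contractile genes of skeletal muscle were lower with silk, at a median of −2.54, with 52 of 55 members negative (adjusted p = 1.4e-29, and adjusted p = 0.097 with an estimated correlation). The skeletal alpha-actin gene acta1.L was at 119.9 ± 51.2 FPKM with silk and 2857 ± 1445 without a device, a difference of −4.47 ± 0.66. The parvalbumin gene pvalb.1.L, for a calcium buffer of fast fibres, was at 50.5 ± 4.96 and 1171 ± 532 (−4.41 ± 0.57), and fast troponin C (tnnc2.L) at 35.8 ± 21.6 and 762.3 ± 214 (−4.53 ± 0.66). The muscle enzymes eno3.L and pgam2.S differed by −4.06 ± 0.59 and −3.81 ± 0.54. Glycolysis and hypoxia genes had a median of −0.88, with 57 of 60 members negative (adjusted p = 8.82e-09, and adjusted p = 0.694 with an estimated correlation, and a median of −1.15 to −0.35 with 1 sample left out). Among them were aldoa.S (−3.76 ± 0.56), gapdh.S (−3.73 ± 0.66) and tpi1.L (−2.61 ± 0.59). Genes of the mitochondrial respiratory chain had a median of −1.04, with 84 of 92 members negative (adjusted p = 1.53e-09, and adjusted p = 0.694 with an estimated correlation). Of these, uqcrb.L and cox6b1.S were listed at 0 in all silk samples and at 15.7 to 18.8 and 30.7 to 50.04 FPKM without a device. In the silk libraries 1 read in a gene of 1 kb was worth 3.388 to 4.545 FPKM, so few reads lie behind these zeros. Over alternative settings the differences ran from −4.15 to −1.94 for uqcrb.L and from −5.36 to −0.72 for cox6b1.S.

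Muscle stem cell and myogenic genes had a median of −0.61, with 27 of 32 members negative (adjusted p = 0.000605, and adjusted p = 0.105 with an estimated correlation). The transcription factor copies mef2c.S and mef2c.L of the muscle lineage differed by −2.48 ± 0.64 and −2.12 ± 0.56. Erythrocyte markers had a median of 0.93, with 21 of 30 members positive (adjusted p = 7.2e-05, and adjusted p = 0.7 with an estimated correlation). The globin genes hbg1.S and hba1.L differed by 2.92 ± 0.95 and 2.26 ± 1.09. Genes of reactive oxygen species production and antioxidant enzymes had a median of 0.79, with 30 of 50 members positive (adjusted p = 0.000676, and adjusted p = 0.7 with an estimated correlation). The gene gclm.L, for a subunit of the enzyme that starts glutathione synthesis, was at 96.5 ± 30.2 FPKM with silk and 24.1 ± 13.4 without a device. Ribosomal protein genes had a relative median of 0.29 and an unscaled median of −0.07, of the other sign (adjusted p = 0.0188, and adjusted p = 0.948 with an estimated correlation), and their call was lost without silk 1, silk 3, no-device 1 or no-device 3 (up to 0.14). Markers of other cell types passed as well. Myeloid leukocyte markers had a median of 0.62, with 23 of 40 members positive (adjusted p = 0.00993, and adjusted p = 0.7 with an estimated correlation), and the call was lost without silk 1 or no-device 1 (up to 0.0915). Retina and pineal photoreceptor genes had a median of 0.57, with 21 of 34 members positive (adjusted p = 0.00528, and adjusted p = 0.7 with an estimated correlation), and the call was lost without no-device 1 (0.0882). Astroglia markers had a median of −0.58, with 24 of 28 members negative (adjusted p = 0.0153, and adjusted p = 0.694 with an estimated correlation, and a median of −0.63 to −0.35 with 1 sample left out), and the call was lost without silk 1, silk 2 or no-device 1 (up to 0.193). In all, 10 lists passed for silk against no device in blastema.

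Adjusted over the list alone, 36 muscle, 13 glycolysis, 6 respiratory chain and 4 myogenic genes were lower. Limma called 0 of 37273 genes, with 2859 at an unadjusted p under 0.05. The smallest adjusted p in limma, 0.0582, was shared by pvalb.1.L, pgam2.S, acta1.L, the Ras-related GTPase gene rrad.L (−4.18 ± 0.57), and ndufa12.S and nat16.S, which were listed at 0 in all silk samples. Among 8546 genes with at least 10 estimated reads on average, a filter added after seeing the data, limma called 134 genes, 2 higher and 132 lower. Of these 26 were muscle genes, and acta1.L, pvalb.1.L, tnnc2.L, eno3.L, pgam2.S, rrad.L and aldoa.S each had adjusted p = 0.00859. Limma-voom on estimated reads called 122 genes, 107 of them shared with that count, and limma with separate libraries called 79. The authors' deposited table has 134 genes with q under 0.05, 35 higher and 99 lower.

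**Figure D3:**
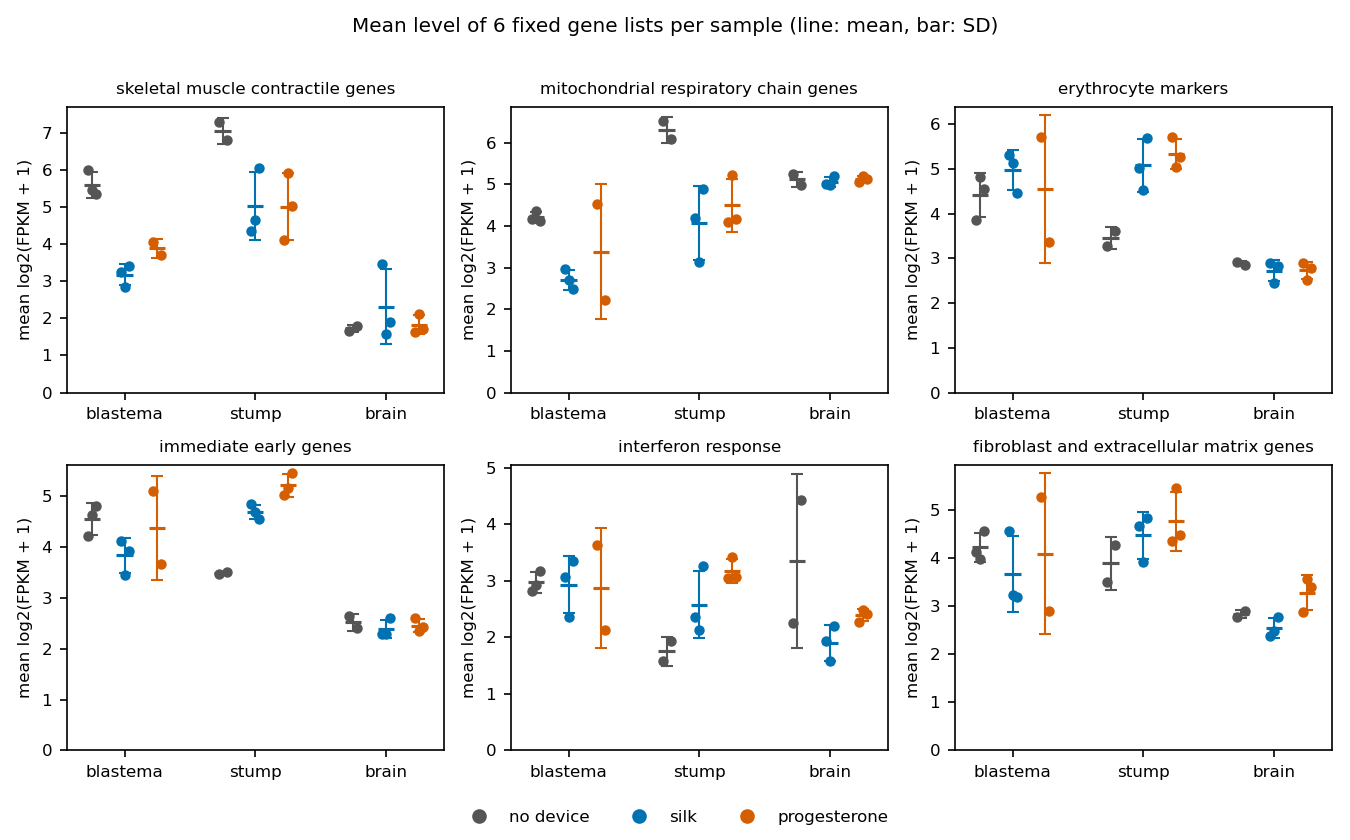
Points are samples, with the mean log2(FPKM + 1) over the members of a gene list on the y axis and the treatment groups of blastema, stump and brain on the x axis; lines are group means and bars are SD. The muscle list lies at 2.86 to 3.42 in blastema silk samples and at 5.36 to 6.003 in blastema samples without a device.

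Whether progesterone in the device changed the blastema relative to no device was tested next (n = 2 and n = 3). The muscle list was lower here too, at a median of −1.83, with 49 of 55 members negative (adjusted p = 9.54e-26, and adjusted p = 0.131 with an estimated correlation). The creatine kinase gene ckm.S was at 306 ± 33.9 FPKM with progesterone and 4322 ± 1550 without a device (−3.74 ± 0.73), the actin-binding xirp1.L differed by −4.08 ± 0.89, and the parvalbumin pvalb.S by −3.51 ± 0.79. The kelch protein gene of striated muscle klhl40.S was listed at 0 in 1 progesterone sample and at 8.54 FPKM in the other, and at 272 to 500.4 FPKM without a device. Glycolysis genes had a median of −0.98, with 54 of 60 members negative (adjusted p = 1.12e-10, and adjusted p = 0.678 with an estimated correlation, and a median of −1.66 to −0.49 with 1 sample left out). Of these, aldoa.S differed by −3.19 ± 0.62 and gapdh.S by −2.70 ± 0.74. Respiratory chain genes had a median of −0.79, with 73 of 92 members negative (adjusted p = 3.97e-05, and adjusted p = 0.808 with an estimated correlation, and a median of −1.65 to 0.43 with 1 sample left out). Their direction was the opposite without progesterone 2, at a median of 0.43 and adjusted p = 0.0475.

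Epidermis markers had a median of 0.39, with 42 of 57 members positive (adjusted p = 0.0133, and adjusted p = 0.207 with an estimated correlation, and a median of 0.23 to 0.56 with 1 sample left out). The junction protein cldn4.S differed by 2.79 ± 0.88 and the epithelial adhesion molecule epcam.S by 2.36 ± 1.01. The call was lost without the merged progesterone sample or no-device 3 (adjusted p up to 0.102). Inflammatory mediators had a median of −0.50, with 35 of 46 members negative (adjusted p = 0.0133, and adjusted p = 0.836 with an estimated correlation, and a median of −1.48 to 0.06 with 1 sample left out). The genes il1b.S, ptgs2.S and cxcl8.L differed by −2.74 ± 1.46, −2.76 ± 1.26 and −2.76 ± 1.43 (−4.65 to −0.84, −5.18 to −0.35 and −4.77 to −0.75 with 1 sample left out), and the call was lost without progesterone 2 or no-device 3 (up to 0.372). Neuron markers had a median of −0.64, with 44 of 55 members negative (adjusted p = 0.0133, and adjusted p = 0.836 with an estimated correlation, and a median of −0.95 to −0.29 with 1 sample left out). The synaptic genes vamp2.L and slc17a7.L differed by −3.50 ± 1.52 (−4.99 to −2.01 with 1 sample left out) and −2.41 ± 0.98, and the call was lost without the merged progesterone sample, no-device 1 or no-device 3 (up to 0.926). Cartilage and bone markers had a median of 0.40, with 29 of 42 members positive (adjusted p = 0.0373, and adjusted p = 0.331 with an estimated correlation, and a median of 0.11 to 0.50 with 1 sample left out), and their call was lost without the merged progesterone sample, no-device 2 or no-device 3 (up to 0.0858).

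Adjusted over the list alone, 27 muscle genes and 1 glycolysis gene were lower. With limma 0 of 37273 genes passed, with 1378 at an unadjusted p under 0.05. The smallest adjusted p in limma was 0.287 for klhl40.S, followed by apln.S (a vascular peptide gene listed at 0 with progesterone), rrad.L (−3.77 ± 0.64), fam102a.L (−3.74 ± 0.71) and ckm.S. Voom called 2 genes, limma with separate libraries 4, and limma with at least 10 reads 0. The authors' deposited table has 630 genes with q under 0.05, 312 higher and 318 lower. Without the merged progesterone sample limma called 1 gene.

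The contribution of the hormone within the device was addressed by comparing progesterone with silk in blastema (n = 2 and n = 3). Muscle genes were higher with progesterone, at a median of 0.50, with 44 of 55 members positive (adjusted p = 0.0289, and adjusted p = 0.95 with an estimated correlation, and a median of 0.09 to 0.91 with 1 sample left out). The Z-disc genes myoz1.L and myoz1.S were at 22.5 ± 15.7 and 16.0 ± 2.92 FPKM with progesterone and 3.62 ± 2.27 and 4.57 ± 1.72 with silk, and pgam2.S at 35.8 ± 2.94 and 10.97 ± 2.89. The muscle call was lost without silk 1, silk 2 or the merged progesterone sample (adjusted p up to 0.327). Erythrocyte markers had a median of −0.97, with 20 of 30 members negative (adjusted p = 0.00871, and adjusted p = 0.95 with an estimated correlation, and a median of −2.41 to 0.49 with 1 sample left out). The globin hbg1.S differed by −2.45 ± 1.06 (−3.7 to −1.19 with 1 sample left out). The globin hba1.S, at 169.5 and 2624 FPKM in the 2 progesterone samples, changed sign without the lower one, and hba3.L was at 0.89 and 8.09 with progesterone and listed at 0 with silk. The erythrocyte call was lost without silk 1 or silk 2 (up to 0.0926), and without progesterone 2 the list passed in the other direction, at a median of 0.49 (adjusted p = 0.0112). Antioxidant genes had a median of −0.64, with 30 of 50 members negative (adjusted p = 0.00871, and adjusted p = 0.95 with an estimated correlation, and a median of −1.56 to 0.41 with 1 sample left out). The genes gclm.L and gclc.L differed by −2.0 ± 0.78 and −2.15 ± 0.77 and gpx4.S, in the other direction, by 3.01 ± 1.09 (−3.0 to −0.99, −3.38 to −0.91 and 1.99 to 4.18 with 1 sample left out), and the call was lost without silk 1 or progesterone 2 (up to 0.153). Ribosomal protein genes had a median of −0.41, with 62 of 114 members negative (adjusted p = 0.00914, and adjusted p = 0.95 with an estimated correlation, and a median of −1.92 to 1.05 with 1 sample left out). The gene rpl34.S differed, in the other direction, by 1.57 ± 0.83 (0.61 to 2.53 with 1 sample left out). Listed at 0 in progesterone 2 were rpl35.L, rps12.L and rpl37.S, at 769.1, 648.1 and 617.7 FPKM in the merged progesterone sample and at 339.1 to 418.3, 200.8 to 308.2 and 163.9 to 195.7 with silk, and all 3 changed sign without progesterone 2. The ribosomal call was lost without silk 1 or silk 3 (up to 0.0926), and without progesterone 2 this list too passed in the other direction, at a median of 1.05 (adjusted p = 4.41e-30). The direction of both lists thus rests on 1 of 2 progesterone samples.

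Limma called 0 of 37273 genes in this comparison, with 2102 at an unadjusted p under 0.05, and voom, separate libraries and the 10-read filter called 0 too. The smallest adjusted p in limma, 0.36, was that of hes4.L, which like ndufa12.S, nat16.S, mpc1.S and znf330.S was listed at 0 in all silk samples. The authors' deposited table has 2 genes with q under 0.05. Without the merged progesterone sample limma called 1 gene.

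In the stump, silk was first compared with no device (n = 3 and n = 2). Genes of the respiratory chain were lower with silk, at a median of −2.67, with 92 of 92 members negative (adjusted p = 5.25e-63, and adjusted p = 0.423 with an estimated correlation). The ATP synthase subunit genes atp5h.S and atp5c1.L were at 8.77 ± 2.71 and 16.1 ± 6.14 FPKM with silk and 69.2 ± 11.3 and 97.1 ± 18.4 without a device, and the complex I gene ndufa9.L at 8.99 ± 7.38 and 88.5 ± 16.3. Muscle genes had a median of −2.93, with 46 of 51 members negative (adjusted p = 3.04e-35, and adjusted p = 0.423 with an estimated correlation). The myosin light chain myl1.L was at 160 ± 77.6 against 1866 ± 770 FPKM (−3.62 ± 0.80), and myl1.S and the fast troponin I gene tnni2.L differed by −3.38 ± 0.83 and −2.74 ± 0.69. Glycolysis genes had a median of −0.99, with 36 of 59 members negative (adjusted p = 5.56e-10, and adjusted p = 0.423 with an estimated correlation). Of these, pgk1 differed by −4.30 ± 0.87, gpi.L by −2.97 ± 0.68 and gapdh.S by −3.09 ± 0.73. Epidermis markers had a median of −1.62, with 36 of 51 members negative (adjusted p = 1.68e-09, and adjusted p = 0.653 with an estimated correlation, and a median of −2.49 to −0.82 with 1 sample left out). The keratin krt24.L differed by −3.98 ± 1.1, and krt17.L was listed at 0 in all silk samples. No-device 2 stood apart in the epidermis list, at a mean level of 4.007 against 2.102 in the merged no-device sample and 1.777 to 2.204 with silk. The unscaled epidermis median was −1.1 with all samples and −0.06 without no-device 2. Ribosomal protein genes had a median of −0.81, with 95 of 114 members negative (adjusted p = 5.56e-10, and adjusted p = 0.835 with an estimated correlation). The genes rplp0.S and rpl8.L differed by −1.0 ± 0.58 and −1.17 ± 0.67.

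Erythrocyte markers were higher with silk in stump, at a median of 1.61, with 26 of 30 members positive (adjusted p = 4.55e-07, and adjusted p = 0.646 with an estimated correlation). The anion exchanger of red cells slc4a1.L was at 65.5 ± 25.9 FPKM with silk and 7.29 ± 0.513 without a device (2.94 ± 0.58), and the erythroid transcription factors gata1.S, gata1.L and nfe2.L differed by 2.77 ± 0.58, 2.35 ± 0.53 and 2.70 ± 0.56. Immediate early genes had a median of 0.82, with 44 of 52 members positive (adjusted p = 1.8e-06, and adjusted p = 0.461 with an estimated correlation). The gene fos.L was at 102.5 ± 55.6 against 5.09 ± 2.23 FPKM (3.99 ± 0.63). The heat shock gene hsp70.L appears as 3 near-identical loci that share reads, so their separate values are uncertain, at 343 ± 294, 293.2 ± 204 and 215.8 ± 147 FPKM with silk and 3.16 ± 1.73, 3.12 ± 1.68 and 3.22 ± 0.325 without a device. Neuron markers had a median of 0.77, with 39 of 44 members positive (adjusted p = 0.000224, and adjusted p = 0.775 with an estimated correlation, and a median of 0.58 to 1.19 with 1 sample left out). Schwann cell and myelin genes had a median of 0.57, with 30 of 34 members positive (adjusted p = 0.000748, and adjusted p = 0.497 with an estimated correlation, and a median of 0.46 to 0.92 with 1 sample left out). V-ATPase and gap junction genes had a median of −0.68, with 28 of 43 members negative (adjusted p = 0.00214, and adjusted p = 0.835 with an estimated correlation, and a median of −0.88 to −0.44 with 1 sample left out), and the call was lost without no-device 2 (adjusted p 0.0864). Myogenic genes had a relative median of −0.45 and an unscaled median of 0.06, of the other sign (adjusted p = 0.00554, and adjusted p = 0.497 with an estimated correlation, and a median of −0.66 to −0.28 with 1 sample left out), and the call was lost without silk 3 or the merged no-device sample (up to 0.156). In all, 11 lists passed for silk against no device in stump.

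**Figure D4:**
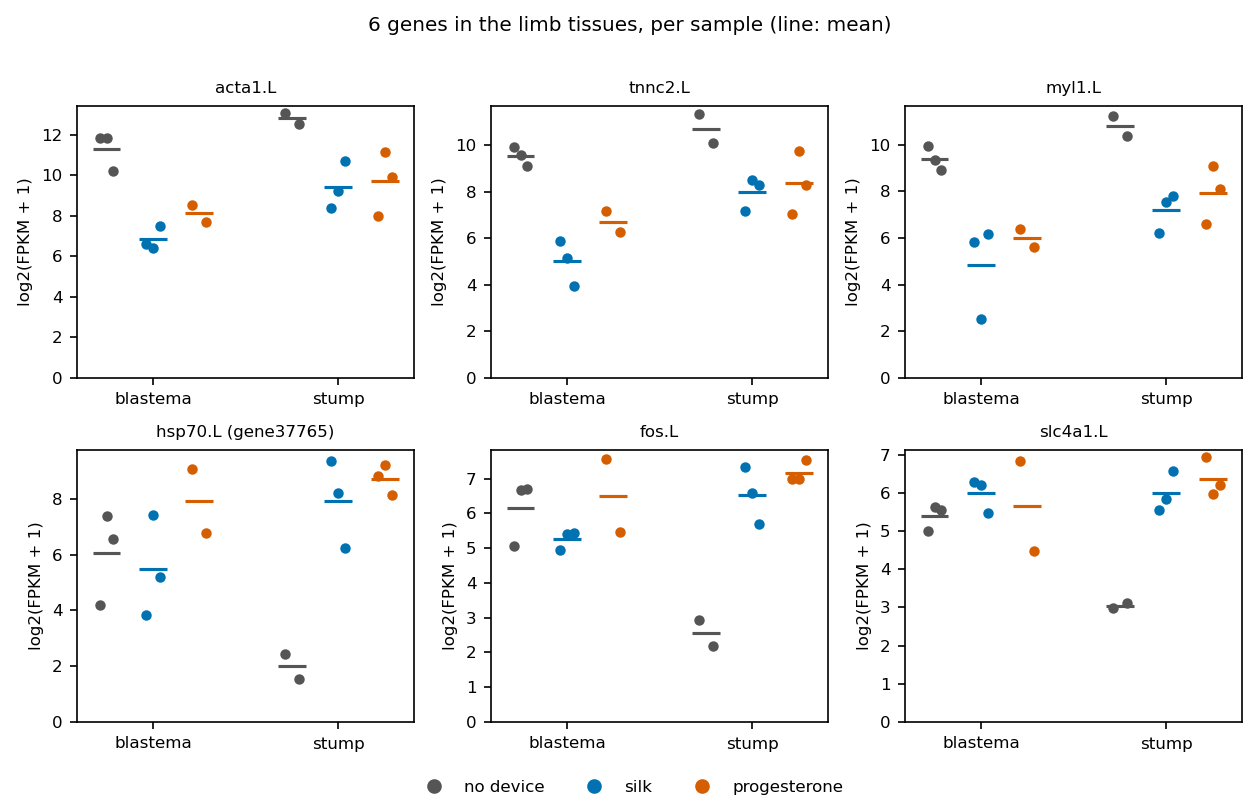
FPKM on a log scale (y axis) of acta1.L, tnnc2.L, myl1.L, hsp70.L, fos.L and slc4a1.L in each blastema and stump sample, by treatment (x axis); points are samples and lines are means. In stump, fos.L lies at 50.7 to 161.2 FPKM with silk, 125.4 to 185.6 with progesterone and 3.51 to 6.67 without a device.

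Adjusted over the list alone, 63 respiratory chain, 30 muscle and 7 glycolysis genes were lower with silk in stump, 16 erythrocyte genes were higher, and 19 immediate early genes were higher and 1 lower. Limma called 0 of 29972 genes, with 3892 at an unadjusted p under 0.05. The smallest adjusted p in limma, 0.12, was shared by the 3 hsp70.L loci, fos.L and lrrc20.L, which was listed at 0 in all silk samples. With at least 10 estimated reads limma called 151 genes, 110 higher and 41 lower, with adjusted p = 0.0247 for fos.L and the hsp70.L loci and 0.0382 for slc4a1.L, atp5h.S and pgk1. Voom called 7496 genes, 93.5% of them higher, and limma with separate libraries 916. The voom fit had no scaling factors, and the median of all genes in limma was 0.52, against 0.06 after median-of-ratios scaling. The excess of higher genes in voom cannot be told apart from such a shift. Voom with at least 5 and 10 reads called 1548 and 911 genes, of which 1344 and 771 were higher. The authors' deposited table has 10873 genes with q under 0.05, 7458 higher and 3415 lower. Without silk 3 limma called 11 genes.

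With progesterone, the stump was likewise compared with no device (n = 3 and n = 2). Respiratory chain genes had a median of −2.32, with 92 of 92 members negative (adjusted p = 4.56e-68, and adjusted p = 0.135 with an estimated correlation). Among them were atp5d.S (22.0 ± 18.9 against 138.2 ± 18.4 FPKM), ndufa4.L (44.3 ± 15.5 against 267.4 ± 10.1) and cytochrome c, cycs.S (35.1 ± 18.2 against 231.3 ± 66.9). Muscle genes had a median of −2.90, with 48 of 51 members negative (adjusted p = 4.67e-49, and adjusted p = 0.135 with an estimated correlation). The genes klhl41.L and pgam2.S differed by −3.24 ± 0.76 and −2.88 ± 0.72. Glycolysis genes had a median of −0.95, with 33 of 59 members negative (adjusted p = 7.22e-09, and adjusted p = 0.265 with an estimated correlation). The gene pgk1 was listed at 0 in all progesterone samples, gpi.L differed by −2.99 ± 0.68 and the phosphofructokinase gene pfkm.L by −2.66 ± 0.67. Epidermis markers had a median of −1.08, with 33 of 51 members negative (adjusted p = 2.78e-07, and adjusted p = 0.76 with an estimated correlation, and a median of −1.95 to −0.33 with 1 sample left out). The keratin krt24.L differed by −3.34 ± 1.1 (−4.53 to −2.18 with 1 sample left out), and the call was lost without no-device 2 (adjusted p 0.214).

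Immediate early genes were higher with progesterone in stump, at a median of 1.24, with 49 of 52 members positive (adjusted p = 4.88e-17, and adjusted p = 0.135 with an estimated correlation). The gene fos.L was at 145.9 ± 34.4 against 5.09 ± 2.23 FPKM (4.62 ± 0.63), and fos.S and fosb.S differed by 3.63 ± 0.61 and 3.56 ± 0.59. Erythrocyte markers had a median of 1.88, with 27 of 30 members positive (adjusted p = 9.05e-12, and adjusted p = 0.314 with an estimated correlation). The gene slc4a1.L was at 84.9 ± 31.7 against 7.29 ± 0.513 FPKM, and gata1.S and nfe2.L differed by 3.25 ± 0.58 and 2.84 ± 0.56. Interferon response genes had a median of 0.70, with 31 of 32 members positive (adjusted p = 2.8e-07, and adjusted p = 0.468 with an estimated correlation). Endothelium markers had a median of 0.45, with 40 of 45 members positive (adjusted p = 0.00177, and adjusted p = 0.135 with an estimated correlation, and a median of 0.15 to 0.75 with 1 sample left out), and their call was lost without no-device 2 (adjusted p 0.129). The hsp70.L loci, with the sharing of reads named above, differed by 6.73 ± 0.85, 6.52 ± 0.86 and 5.89 ± 0.83, and traf3ip3.S was at 68.5 ± 9.89 against 3.47 ± 0.601 FPKM (3.96 ± 0.53).

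Further lists passed in this comparison. Neuron markers had a median of 0.65, with 39 of 44 members positive (adjusted p = 0.00851, and adjusted p = 0.931 with an estimated correlation, and a median of 0.31 to 0.89 with 1 sample left out), and the call was lost without progesterone 1 or no-device 2 (up to 0.191). Inflammatory mediators had a median of 0.37, with 35 of 42 members positive (adjusted p = 0.00628, and adjusted p = 0.931 with an estimated correlation, and a median of 0.12 to 0.71 with 1 sample left out) and matrix proteases a median of 0.22, with 41 of 46 members positive (adjusted p = 0.00716, and adjusted p = 0.76 with an estimated correlation, and a median of 0.11 to 0.47 with 1 sample left out), and both calls were lost without progesterone 2 (0.113 and 0.142). Matrix genes had a median of 0.21, with 61 of 67 members positive (adjusted p = 0.00553, and adjusted p = 0.931 with an estimated correlation, and a median of −0.19 to 0.49 with 1 sample left out), and the call was lost without progesterone 2 or the merged no-device sample (up to 0.93). Ribosomal protein genes had a median of −0.61, with 62 of 114 members negative (adjusted p = 7.81e-06, and adjusted p = 0.931 with an estimated correlation, and a median of −1.03 to −0.32 with 1 sample left out), and the call was lost without progesterone 3 (0.101). Myogenic genes had a median of −0.61, with 15 of 30 members negative (adjusted p = 0.000228, and adjusted p = 0.23 with an estimated correlation, and a median of −0.83 to −0.28 with 1 sample left out). V-ATPase and gap junction genes had a relative median of −0.30 and an unscaled median of 0.27, of the other sign (adjusted p = 0.0145, and adjusted p = 0.931 with an estimated correlation, and a median of −0.69 to −0.09 with 1 sample left out), and the call was lost without progesterone 3 or no-device 2 (up to 0.479). Cartilage and bone markers had a relative median of −0.47 and an unscaled median of 0.09, of the other sign (adjusted p = 0.0204, and adjusted p = 0.931 with an estimated correlation, and a median of −0.77 to −0.07 with 1 sample left out), and the call was lost without progesterone 1 or no-device 2 (up to 0.73).

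Of all lists, 16 passed for progesterone against no device in stump. Adjusted over the list alone, 30 muscle and 6 glycolysis genes were lower, 36 immediate early, 18 erythrocyte and 5 interferon genes were higher, and 0 respiratory chain genes passed. Of 29972 genes limma called 0, with 2953 at an unadjusted p under 0.05 and a smallest adjusted p of 0.132 for the hsp70.L loci, traf3ip3.S and fos.L. With at least 10 estimated reads it called 219 genes, 192 higher and 27 lower, with adjusted p = 0.0108 for fos.L and traf3ip3.S. Voom, without scaling factors, called 1472 genes, 217 of them shared with the 10-read count, and limma with separate libraries 302. The authors' deposited table has 6039 genes with q under 0.05, 3266 higher and 2773 lower.

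Progesterone and silk were then compared directly in the stump (n = 3 and n = 3). Immediate early genes were higher with progesterone, at a median of 0.43, with 47 of 52 members positive (adjusted p = 7.59e-06, and adjusted p = 0.859 with an estimated correlation, and a median of 0.16 to 0.68 with 1 sample left out). The gene ier2.L was at 96.3 ± 44.7 FPKM with progesterone and 29.8 ± 9.13 with silk, and ier2.S at 55.2 ± 9.87 and 22.7 ± 6.44. The call was lost without silk 3 (adjusted p 0.357). Interferon response genes had a median of 0.51, with 29 of 32 members positive (adjusted p = 0.000255, and adjusted p = 0.859 with an estimated correlation, and a median of 0.31 to 0.62 with 1 sample left out). The antiviral GTPase gene mx1 was at 7.24 to 9.38 FPKM with progesterone and 0 to 3.25 with silk, zbp1.L was listed at 0 in all silk samples, and the call was lost without progesterone 2 (0.0518). Inflammatory mediators had a median of 0.41, with 35 of 42 members positive (adjusted p = 0.00166, and adjusted p = 0.859 with an estimated correlation, and a median of 0.15 to 0.66 with 1 sample left out). The NF-kappaB inhibitor nfkbia.L was at 136.1 ± 6.97 and 63.5 ± 5.99 FPKM, and nfkbia.S and the chemokine cxcl8.S differed by 1.24 ± 0.47 and 1.60 ± 0.67. Heat shock and endoplasmic reticulum stress genes had a median of 0.36, with 51 of 62 members positive (adjusted p = 0.00166, and adjusted p = 0.859 with an estimated correlation, and a median of 0.23 to 0.43 with 1 sample left out). The stress transcription factor ddit3.L was at 39.7 ± 9.73 and 10.5 ± 8.97 FPKM. Schwann cell and myelin genes had a median of −0.56, with 23 of 34 members negative (adjusted p = 0.00229, and adjusted p = 0.859 with an estimated correlation). The myelin protein gene mpz.L differed by −1.92 ± 1.06 and fa2h.L by −1.77 ± 0.63 (−2.93 to −0.42 and −2.25 to −1.13 with 1 sample left out).

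Markers of other cell types passed in the same comparison. Neuron markers had a median of −0.34, with 31 of 44 members negative (adjusted p = 0.0422, and adjusted p = 0.859 with an estimated correlation, and a median of −0.67 to −0.05 with 1 sample left out), and the call was lost without silk 1, silk 2 or progesterone 2 (up to 0.762). Neuropeptides had a median of −0.49, with 19 of 24 members negative (adjusted p = 0.00965, and adjusted p = 0.859 with an estimated correlation, and a median of −0.67 to −0.26 with 1 sample left out), and the call was lost without silk 1, silk 3 or progesterone 2 (up to 0.263). Endothelium markers had a median of 0.26, with 38 of 45 members positive (adjusted p = 0.018, and adjusted p = 0.629 with an estimated correlation, and a median of 0.01 to 0.38 with 1 sample left out), and the call was lost without silk 3, progesterone 1 or progesterone 2 (up to 0.751). Matrix genes had a median of 0.19, with 49 of 67 members positive (adjusted p = 0.0275, and adjusted p = 0.859 with an estimated correlation, and a median of −0.12 to 0.42 with 1 sample left out), and the call was lost without silk 2, silk 3 or progesterone 2 (up to 0.422). Epidermis markers had a median of 0.56, with 38 of 51 members positive (adjusted p = 0.0434, and adjusted p = 0.859 with an estimated correlation, and a median of −0.24 to 0.99 with 1 sample left out), and the call was lost without silk 3 or progesterone 1 (up to 0.791). Erythrocyte markers had a median of 0.28, with 25 of 30 members positive (adjusted p = 0.0494, and adjusted p = 0.859 with an estimated correlation, and a median of 0.03 to 0.40 with 1 sample left out), and the call was kept only without progesterone 3 (up to 0.69 otherwise). Ribosomal protein genes had a median of 0.19, with 103 of 114 members positive (adjusted p = 0.00443, and adjusted p = 0.859 with an estimated correlation, and a median of −0.19 to 0.47 with 1 sample left out) and respiratory chain genes a median of 0.32, with 69 of 92 members positive (adjusted p = 0.00665, and adjusted p = 0.859 with an estimated correlation, and a median of −0.03 to 0.53 with 1 sample left out), and these calls were lost without silk 1 or progesterone 2 (up to 0.332) and without silk 2 or progesterone 2 (up to 0.341). Silk 1, silk 3 and progesterone 1 stood apart from the other 3 samples: this split gave 745 genes in limma, where progesterone against silk gave 0, and neuron marker levels were 2.30, 2.24 and 2.45 in these and 1.57, 1.15 and 1.83 in the others.

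In all, 13 lists passed for progesterone against silk in stump. Limma called 0 of 29972 genes, with 1149 at an unadjusted p under 0.05, voom and the 10-read filter called 0 and limma with separate libraries 9. The smallest adjusted p in limma, 0.103, was that of gnrh1.L, a gonadotropin-releasing hormone gene listed at 0 in all progesterone samples and at 9.05 to 11.8 FPKM with silk. Next were carm1.L, sult1c1.L and polr2c.S, listed at 0 in all silk samples, and ube2s.L (2.55 ± 0.52). Without silk 3 limma called 3 genes and without progesterone 2 it called 1. The authors' deposited table has 26 genes with q under 0.05, of which 23 were higher with silk.

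The brain lies far from the device, and silk was compared there with no device (n = 3 and n = 2). The library labelled brain silk 3 is counted in the silk group although it was near-identical to the 2 libraries merged in the no-device group, so the 2 groups are not shown to hold separate samples. Interferon response genes had a median of −1.28, with 26 of 26 members negative (adjusted p = 2.96e-09, and adjusted p = 0.912 with an estimated correlation, and a median of −2.23 to −0.16 with 1 sample left out). The antiviral genes mx1, dhx58.L and parp9.L were at 0 to 1.79, 3.20 to 5.65 and 0 to 1.09 FPKM with silk and at 3.50 to 147.9, 8.07 to 93.06 and 1.32 to 8.34 without a device. This list rested on brain no-device 2, whose mean level of 4.44 stood above 2.26 in the merged no-device sample, with adjusted p 0.223 without it. Muscle genes had a median of 0.74, with 19 of 23 members positive (adjusted p = 1.89e-05, and adjusted p = 0.912 with an estimated correlation, and a median of 0.06 to 1.30 with 1 sample left out). They rested on brain silk 1, whose mean level was 3.48 (adjusted p 0.627 without it), and mylpf.S was at 1.46 to 13.9 FPKM with silk and 0 to 0.315 without a device. Myeloid leukocyte markers had a median of −0.30, with 24 of 27 members negative (adjusted p = 0.0361, and adjusted p = 0.912 with an estimated correlation, and a median of −0.64 to −0.15 with 1 sample left out). The genes cybb.L and cd74.L differed by −0.97 ± 0.31 and −0.84 ± 0.33, and the call was lost without silk 2 or no-device 2 (up to 0.542).

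Limma called 0 of 27157 genes for silk against no device in brain, with 1278 at an unadjusted p under 0.05, voom and the 10-read filter 1 each and separate libraries 5. The named genes with the smallest p were rgs18.S, slurp1l.S, cib1.S and ggh.2.L, listed at 0 in all silk samples and at most 3.79 FPKM without a device, and the cyclin ccnd1.L (−1.59 ± 0.25, limma adjusted p = 0.391). Without the library labelled brain silk 3 limma called 26 genes and without the merged no-device sample 13. The authors' deposited table has 9 genes with q under 0.05.

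For progesterone against no device in brain (n = 3 and n = 2), fibroblast and extracellular matrix genes were higher. This list had a median of 0.48, with 44 of 53 members positive (adjusted p = 1.35e-09, and adjusted p = 0.995 with an estimated correlation, and a median of 0.26 to 0.58 with 1 sample left out). The collagen genes col6a1.L and col3a1.S were at 10.2 ± 1.97 and 18.8 ± 9.92 FPKM with progesterone and 4.37 ± 1.09 and 6.25 ± 0.948 without a device, and the collagen crosslinking enzyme lox.L at 4.70 ± 1.33 and 1.73 ± 0.488. Interferon response genes had a median of −0.96, with 25 of 26 members negative (adjusted p = 5.09e-08, and adjusted p = 0.995 with an estimated correlation, and a median of −1.89 to 0.22 with 1 sample left out). The gene stat2.S differed by −1.80 ± 0.84 (−3.53 to −0.06 with 1 sample left out), and the call was lost without no-device 2 (adjusted p 0.138). Epidermis markers, among them keratins that other epithelia also express, had a median of 0.32, with 17 of 21 members positive (adjusted p = 0.0017, and adjusted p = 0.995 with an estimated correlation). The keratins krt8.L and krt19.L differed by 0.79 ± 0.37 (0.39 to 1.19 with 1 sample left out) and 1.46 ± 0.81, and the call was lost without the merged no-device sample (0.0624). Neuropeptides and pituitary hormones had a median of −0.30, with 44 of 53 members negative (adjusted p = 0.00622, and adjusted p = 0.995 with an estimated correlation). Growth hormone (gh1.S) was at 0 to 5.80 FPKM with progesterone and 20.1 to 78.4 without a device, vasopressin (avp.L), in the other direction, at 70.4 ± 23.4 and 27.8 ± 25.4 (a difference of 1.61, and 0.56 to 2.67 with 1 sample left out), and the call was lost without the merged no-device sample or progesterone 2 (up to 0.142).

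For progesterone against no device in brain, limma called 0 of 27157 genes, with 789 at an unadjusted p under 0.05, voom and the 10-read filter 0 and separate libraries 2. The named genes with the smallest p were cox19.S (−1.25 ± 0.23), ackr4.L (1.40 ± 0.28), lsm3.L (−1.46 ± 0.29), atp2b1.L (1.24 ± 0.25) and hspb8.L (−1.25 ± 0.26), none of which passed. Without the merged no-device sample limma called 4 genes, and without no-device 1 or no-device 3 alone 1. The authors' deposited table has 38 genes with q under 0.05, 29 higher and 9 lower.

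For progesterone against silk in brain (n = 3 and n = 3), the matrix list was higher with progesterone. It had a median of 0.57, with 49 of 53 members positive (adjusted p = 2.86e-12, and adjusted p = 0.864 with an estimated correlation). The gene col6a1.L was at 10.2 ± 1.97 FPKM with progesterone and 2.27 ± 1.04 with silk (1.82 ± 0.29), the proteoglycan bgn at 13.6 ± 0.983 and 4.26 ± 1.48 (1.5 ± 0.24), and lox.L and col6a2.L differed by 1.38 ± 0.27 and 1.21 ± 0.27. Epidermis markers had a median of 0.63, with 20 of 21 members positive (adjusted p = 6.61e-05, and adjusted p = 0.864 with an estimated correlation, and a median of 0.24 to 0.78 with 1 sample left out). The keratin krt19.L was at 72.5 ± 17.3 and 17.5 ± 17.7 FPKM, and cldn4.L differed by 1.56 ± 0.28. Matrix proteases and their inhibitors had a median of 0.29, with 31 of 39 members positive (adjusted p = 0.0112, and adjusted p = 0.864 with an estimated correlation). The cathepsin gene ctsl.L was at 2.80 to 3.82 FPKM with progesterone and 0 to 0.42 with silk, and the call was lost without silk 2 or progesterone 2 (adjusted p up to 0.0976). Muscle genes had a median of −0.61, with 19 of 23 members negative (adjusted p = 0.000756, and adjusted p = 0.864 with an estimated correlation, and a median of −0.96 to 0.07 with 1 sample left out). They rested on brain silk 1 (0.98 without it), and mylpf.S differed by −1.76 ± 0.72 (−2.25 to −0.93 with 1 sample left out). Neuropeptides had a relative median of −0.09 and an unscaled median of 0.03, of the other sign (adjusted p = 0.0461, and adjusted p = 0.864 with an estimated correlation, and a median of −0.37 to −0.03 with 1 sample left out). The gene nts.L differed by −0.87 ± 0.28, and the call was lost without silk 2, silk 3, progesterone 2 or progesterone 3 (up to 0.567).

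Limma called 6 of 27157 genes between progesterone and silk in brain, each with adjusted p = 0.0336, and 2154 had an unadjusted p under 0.05. Higher with progesterone were gene25230, at 11.3 to 27.1 FPKM against 0 to 0.25, and gene27111, gene22440 and gene4535, which were listed at 0 in all silk samples and reached 4.11, 5.25 and 9.24 FPKM with progesterone. Lower were LOC108716543 and gene20964, listed at 0 in all progesterone samples and at up to 11.8 and 3.43 FPKM with silk. None of the 6 has a name that tells its function. Voom called 2 genes, the 10-read filter 1 (gene4535, limma adjusted p = 0.00601) and separate libraries 9. The count was 0 without silk 1, silk 2, progesterone 1 or progesterone 2, and 72 without the library labelled brain silk 3, which was near-identical to no-device libraries. Adjusted over the list alone, 17 matrix genes were higher. The authors' deposited table has 35 genes with q under 0.05, 4 higher and 31 lower with silk.

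Because progesterone acts through nuclear receptors, the progesterone receptor gene pgr and the steroid-responsive genes klf9, tsc22d3 and zbtb16 were read in every comparison, and fkbp5 was not analysed here. Over the 9 comparisons 54 values were obtained and 0 passed in limma. Against no device they ran from −0.97 to 0.22 with silk and −1.16 to 0.64 with progesterone in blastema, from 0.45 to 1.47 and −0.01 to 1.88 in stump, and from −0.39 to 0.11 and −0.24 to 0.16 in brain. Between progesterone and silk they ran from −0.75 to 0.59 in blastema, −0.59 to 0.41 in stump and −0.04 to 0.35 in brain. The highest values were those of tsc22d3.L in stump, at 160.2 ± 77.7 FPKM with silk, 197.3 ± 44.6 with progesterone and 53.5 ± 19.1 without a device, with limma adjusted p = 0.357 and 0.389, and 0.0382 and 0.0383 in voom.

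Whether the device effects differed between blastema and stump was tested as an interaction, with blastema and stump samples taken as independent. For silk minus no device, fos.L, fosb.L and atf3.S differed between blastema and stump by −4.87 ± 0.97, −4.08 ± 0.85 and −3.76 ± 0.83, the keratin krt24.L by 5.55 ± 1.30, the ATP synthase gene atp5h.S by 2.62 ± 0.78 and the neuronal growth protein gene gap43.L by −4.26 ± 1.18. None of these passed over 41423 genes. Voom, without scaling factors, called 1903 genes, limma with separate libraries 28 and the 10-read filter 0. Limma at the main setting called 1 gene, with 4426 at an unadjusted p under 0.05. This gene, gene27419, was listed at 0 in all blastema silk samples and all stump samples without a device, and had 26.2 ± 22.5 FPKM in blastema without a device and 19.5 ± 12.1 in stump with silk. For progesterone minus silk the same gene was the 1 call (limma adjusted p = 0.0305), with 2328 genes at an unadjusted p under 0.05, where voom and the 10-read filter called 0 and separate libraries 4. Of named genes the smallest p were those of ndufa12.S, mpc1.S, hes4.L, pet100.L and thap11.L, all listed at 0 in blastema silk samples, and the interferon regulator irf1.L differed by −2.03 ± 0.88 (−3.12 to −0.95 with 1 sample left out).

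The effects of both device groups against the same no-device samples were compared across genes, which are not independent replicates. In stump the covariance of the log2 differences was 0.786, where unchanged groups against shared controls gave 0.433, and the correlation was 0.762 against 0.6. In blastema the covariance was 0.379 against 0.389 and in brain 0.091 against 0.143, with correlations of 0.442 and 0.443 against 0.447 and 0.601. The no-device samples are too few to be split, so part of the excess in stump may come from the shared controls.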

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

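All tests of technical explanations here, except the splits of samples without a read filter, were chosen after the result was seen. The results below come from the test of whether a device effect differed between blastema and stump, with positive values where the effect, relative to all genes for lists, was higher in blastema.

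One gene without a name, gene27419, differed by −8.42 for silk minus no device (limma adjusted p = 0.0405) and by 8.61 for progesterone minus silk (0.0305). It was listed at 0 in every library of 3 of the 6 limb groups, so its fold depends on the pseudocount.

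For silk minus no device, the median over list members of the per-gene difference between blastema and stump effects, relative to that of all genes, was 1.62 for respiratory chain genes (camera adjusted p = 7.27e-20), 1.66 for epidermis markers (3.79e-13), 1.11 for ribosomal protein genes (3.29e-12), 0.99 for antioxidant genes (4.29e-05) and 0.43 for V-ATPase and gap junction genes (0.0273). It was −1.13 for immediate early genes (1.52e-09), −0.98 for neuron markers (6.21e-05), −0.78 for Schwann cell and myelin genes (0.000709) and −0.31 for astroglia markers (0.0456). Without scaling to all genes, whose median was −0.85, the V-ATPase median was −0.42, of the other sign, and the antioxidant median 0.14. With 1 sample left out, medians ran from 0.83 (without stump no-device 2) to 2.79 for epidermis, −1.24 to −0.57 for neuron, 0.32 to 0.81 for V-ATPase and −0.66 to −0.06 for astroglia genes. The V-ATPase call was lost without blastema silk 1, stump silk 2 or stump no-device 2 (up to 0.336) and the astroglia call without any 1 of 7 of the 11 samples (up to 0.235). With an estimated correlation the smallest adjusted p was 0.647.

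For progesterone minus silk, it was −0.70 for ribosomal protein genes (1.97e-05), −0.92 for interferon response genes (0.000355), −0.83 for antioxidant genes (0.000355), −1.09 for erythrocyte markers (0.000608), −0.78 for inflammatory mediators (0.00124), −0.59 for heat shock genes (0.0089) and −0.56 for myeloid markers (0.0454). With 1 sample left out these medians ran, in the same order, from −2.1 to 0.79, −1.61 to −0.26, −1.49 to −0.18, −2.42 to 0.20, −1.25 to −0.09, −1.04 to −0.05 and −0.85 to −0.11. All 7 calls were lost without blastema progesterone 2, where the ribosomal list passed in the other direction, at 0.79 (7.6e-14). Further losses were the ribosomal call without stump progesterone 2, the inflammatory call without blastema silk 1, the heat shock call without blastema silk 1 or stump progesterone 3, and the myeloid call without blastema silk 1, stump silk 2 or stump progesterone 2. With an estimated correlation the smallest adjusted p was 0.933.

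The first pattern weighed is the near-identical libraries. A single library deposited more than once is excluded, because the share of reads on smad4.1.S differed at least 1.235-fold in each of the 5 pairs. With the estimated reads taken as counts, each difference was beyond counting error. RNA of one animal in more than one library would give what was seen: the library labelled brain silk 3 differed from brain no-device 1 at 0.2968% of genes and from the other brain silk libraries at 3.33% and 5.31%. Animals that were alike stay open, since the labels name no animals and the other brain pairs differed at 1.559% of genes or more. A wrong label of brain silk 3 was not tested apart from this.

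The second pattern is the share of reads on smad4.1.S. Expression of this copy alone cannot be told apart from other sources. The values argue against a like rise of both copies: smad4.1.S ran from 105 to 80896 FPKM, smad4.1.L from 1.6 to 9.96. The share differed 14.18-fold between the library labelled brain silk 3 and brain no-device 3, alike in other genes. Both pairs over 2-fold hold brain silk 3, and near-identical pairs within groups differed 1.235-fold to 1.991-fold. A step of library preparation that also lowers the number of reads is a candidate source: the library with the largest share had the fewest reads in 6 of 9 groups, where chance gives 3 (exact binomial test, one-sided p = 0.042). No sequence of this gene model was examined, and treatment stays open. Every share over 10% was in a device library. In blastema, stump and brain the lowest device shares were 2.014%, 0.713% and 0.558%, and the highest without a device 1.099%, 0.128% and 0.09955%. Across tissues, 6 device libraries lay within the 0.520% to 1.099% of blastema without a device.

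The third pattern is the lower level of muscle genes in the device groups of blastema and stump. Low depth as the whole cause stays open, although muscle genes with at least 10 estimated reads had medians of −2.35 or lower in all 4 comparisons. That minimum is a mean over all samples of a tissue. Genes high without a device can pass it on those samples alone, so the test cannot exclude low depth. A few loci taking most of the reads are excluded as the whole cause, since the medians were −1.74 or lower after median-of-ratios scaling. Less muscle in the dissected tissue, with a like rise of all other cell types, stays open: the extremes of the 8 marker lists lay 2 to 3.61 standard errors apart. A treatment effect on muscle genes stays open too and cannot be told apart from tissue composition here.

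For splits of the 6 samples into other groups of the same sizes there are 10 splits, too few for a share under 0.05. For silk against no device in blastema limma gave 0 genes in the real split and at most 0 in the others, so all 10 gave as many, and with at least 10 estimated reads 134 and at most 0, so 1 did. For progesterone against silk in brain the real split gave 6 genes and the highest other 14, and 3 splits gave as many. For progesterone against silk in stump the real split gave 0 genes and all 10 gave as many. The highest other, 745, set silk 1, silk 3 and progesterone 1 apart from the rest, so these samples differ along something other than treatment.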

How the results depend on the processing

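Chosen after seeing the data were separate near-identical libraries, the block with these, the 10-read filter, both scalings, the pseudocount of 5, voom with read minimums and leaving out a merged sample. Not run, since the values are not counts, were RLE size factors and upper-quartile factors in a count fit, the DESeq2 Wald test, and the comparison of blastema with stump. The planned replicate block was not run on merged samples, which have 2 replicate numbers. Where a count moved, the cause was not tested, unless fewer genes or samples entered by construction. Counts below are genes called, in the order given, against 0 in limma for every comparison except 6 for progesterone against silk in brain and 1 for each interaction; counts not named stayed within 1.5 times of these.

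In blastema, silk against no device gave 216 with the stricter filter, 122 with voom, 142 with only the compared groups, 288 with a pseudocount of 0.1, 5 with trend and robust on, 79 with separate libraries, 134 with at least 10 reads, 117 with a pseudocount of 5, and 118 and 104 with voom at 5 and 10 reads. Progesterone against no device gave 2 with voom, 4 with separate libraries, and 1 and 10 with voom at 5 and 10 reads.

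In stump, silk against no device gave 17 with the stricter filter, 7496 with voom, 386 with only the compared groups, 27 with a pseudocount of 0.1, 916 with separate libraries, 151 with at least 10 reads, and 1548 and 911 with voom at 5 and 10 reads. Progesterone against no device gave 8, 1472 and 10 with the first 3 of these, 8 with trend and robust on, 302 with separate libraries, 219 with at least 10 reads, 81 with a pseudocount of 5, and 1737 and 1806 with voom at 5 and 10 reads. Progesterone against silk gave 31 with the stricter filter, 132 with a pseudocount of 0.1 and 9 with separate libraries.

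In brain, silk against no device gave 14 with the stricter filter, 1 with voom, 35 with a pseudocount of 0.1, 5 with separate libraries, 1 with at least 10 reads and 1 with voom at 10 reads. Progesterone against no device gave 6 with a pseudocount of 0.1 and 2 with separate libraries. Progesterone against silk gave 17 with the stricter filter, 2 with voom, 13 with only the compared groups, 0 against a fold of 1.5, 62 with a pseudocount of 0.1, 3 with trend and robust on, 1 with at least 10 reads, 0 with a pseudocount of 5, and 0 and 2 with voom at 5 and 10 reads.

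The interaction for silk gave 9 with the stricter filter, 1903 with voom, 12 with only the compared groups, 0 against a fold of 1.5, 44 with a pseudocount of 0.1, 3 with trend and robust on, 28 with separate libraries, 0 with at least 10 reads, 0 with a pseudocount of 5, 565 and 330 with voom at 5 and 10 reads, and 0 and 3 after median-of-ratios and upper-quartile scaling. That for progesterone minus silk gave 13 with a pseudocount of 0.1, 4 with separate libraries, and 0 with voom at any minimum, at least 10 reads, a pseudocount of 5 and either scaling.

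The covariance of the device effects in stump was 0.57 without a filter, 0.964 with the stricter one, 1.03 with at least 10 reads, 1.01 and 1.04 after median-of-ratios and upper-quartile scaling, and 2.2 and 0.299 with pseudocounts of 0.1 and 5. With these pseudocounts it was 1.15 and 0.129 in blastema and 0.304 and 0.027 in brain. Unchanged groups against shared controls were simulated at the main setting only, so covariances at other settings cannot be set against a no-change value. Of the gene lists 73 passed over 9 comparisons, 0 with an estimated correlation and 11 with fry.

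Within a tissue, replicate numbers did not pair samples of different treatments: deviations of same-numbered libraries correlated between −0.08 and 0.15, and no comparison had every pair over 0.1. Whether same-numbered libraries of different tissues were paired, as by a shared frog, was not tested. With the replicate block and separate libraries, stump gave 904 genes for silk and 132 for progesterone against no device, brain 0 for progesterone against silk, and the silk interaction 25.

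With 1 sample left out, a lone sample of a group being assumed to vary like the others, counts in blastema ran from 0 to 0 for silk and 0 to 1 for progesterone against no device and 0 to 1 between them. In stump they ran from 0 to 11, 0 to 0 and 0 to 3 in the same order, and in brain from 0 to 26, 0 to 4 and 0 to 72. Interactions ran from 0 to 5 for silk and 0 to 45 for progesterone minus silk, covariances from 0.317 to 0.544 in blastema, 0.739 to 1.006 in stump and 0.084 to 0.29 in brain, and lists from 63 to 95.

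Of 6385 values of all genes named by the rule, steroid genes apart, 18 changed direction, in 10 of 283 pairs of gene and comparison. The genes printed, 162 of these pairs, were chosen after this was partly seen, and 9 of their 3546 values changed direction, all for progesterone against silk in blastema. There hba3.L had −0.11 and rps12.L 0.08 with voom. Without progesterone 2, hba1.S, rpl35.L, rps12.L and rpl37.S had 0.35, 1.04, 1.46 and 1.78, and without the merged progesterone sample −3.59, −8.55, −7.88 and −7.49. With 1 sample left out, 26 of the 162 printed values moved by over 1.5 times. With voom 54 of the printed genes gained and 5 lost a call, with separate libraries 51 and 3, and with 1 library left out 8 and 23 of 1158 values. Of 666 steroid gene values in other settings 59 changed sign and 2 passed. Depth limits the shallow blastema libraries most, where a gene of 1 kb with 1 read has up to 5.61 FPKM.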
